A study of Mus musculus with 2 samples.

How the data were processed

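Single-cell RNA sequencing libraries of dissociated mouse tumours were compared between 2 genotypes, wild type (WT) and Cdh5-cre Myct1 fl/fl. In the second genotype, called the Myct1 knockout here, Cre recombinase is expressed from the promoter of the endothelial cadherin gene Cdh5 and acts on a floxed Myct1 allele. The sample label spells the driver Cdh-cre, and the spelling Cdh5-cre of the series title was used. Each genotype was represented by 1 droplet library, and each library held cells pooled from the tumours of 4 mice, digested with collagenase, dispase and DNase. The tumour model, any sorting of cells and the floxed exon are not given in the sources used here. Because a genotype had 1 library, no test, p-value or standard error was computed: cells are not replicates, the comparison is of 2 libraries, and a difference of library or batch cannot be told apart from genotype.

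The authors deposited 1 table of UMI counts per library, with genes against cell barcodes, made with Cell Ranger 2.1.1 and the mm10 genome according to the submitters' processing notes. The annotation release is not given in the sources used here. The deposited values were whole counts with no normalisation, and the listed genes added up to the table's own total for every barcode. Every listed gene reached 4 UMIs in at least 1 barcode, with 1695 WT genes and 1586 knockout genes exactly at that maximum, so genes under it were taken to have been left out of each table before deposit. This left 9127 gene symbols in both tables, 1376 in the WT table alone and 536 in the knockout table alone. Comparisons between libraries used the shared symbols.

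Barcodes with fewer than 200 detected genes (1106 WT, 1955 knockout) were left out; their median mitochondrial share was 95.4% in WT and 95.5% in the knockout. A further 1654 WT and 523 knockout barcodes with over 10% mitochondrial UMIs were left out, which kept 8120 and 8222. Doublets were scored within each library against simulated sums of pairs of cells, by the nearest-neighbour score of Scrublet written anew, and cells scoring above 0.3 were left out (250 WT, 264 knockout). That fixed threshold was chosen after the automatic threshold for the WT library had been seen. The 7870 WT and 7958 knockout cells left were log-normalised and clustered together without batch integration, from 2000 variable shared genes, 40 principal components, 20 neighbours and Leiden resolution 1. Clusters were named from marker sets fixed before the files were seen: a type needed at least 3 markers at 3 times their level in the other cells, at least 20 CPM (counts per 10 to the power of 6 counts) and detection in at least 10% of the cluster. The naming rule was amended after the clusters had been seen, to withhold a name where the genes highest in a cluster belonged more to another type and, in clusters of very low depth, where they belonged equally to another type. Unnamed clusters with at least 200 CPM of both Krt8 and Krt18 and under 20 CPM of Cdh5 were treated together as Krt8 and Krt18 positive. Endothelial cells were clustered again on their own with a marker limit of 1.5 times. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9 were used.

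Within a cell class, counts were summed per library and expressed as CPM of the sum. The log2 ratio of knockout over WT carries an exact conditional binomial 95% interval for 2 Poisson counts, levels carry exact Poisson intervals and shares carry exact Clopper-Pearson intervals. These intervals and the limit of 3 counts for a share of 0 cover counting error only, not variation between mice or libraries. Genes were counted as at least 2-fold different where the level reached 100 CPM in 1 library and the interval excluded no difference. Named genes followed a rule fixed beforehand: the 12 largest ratios in each direction by the interval bound nearest 0 in endothelial cells, and 5 in other cell sets, without predicted gene symbols. A gene whose level in another class of at least 20 cells was over 3 times its endothelial level could be set by free RNA in the droplets. Such genes were counted apart, with the 3 largest per direction named. Classes with fewer cells were not part of this check. For each gene list fixed beforehand, members with at least 20 UMIs over both libraries were used, members at least 1.5-fold different with an interval excluding no difference were counted, and up to 4 members with the largest ratios were named. The list median was placed among 10000 random lists of the same size matched on expression, and its percentile describes these libraries only. The lists covered endothelial identity and subtypes, junctions, matrix, antigen presentation, interferon, cytokines, proliferation, metabolism, transcription factors, stress, RNA quality, sex-linked genes, the Myct1 neighbourhood and immune cell states. The same steps were applied to other sets of at least 50 cells in each library.

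Transcript lengths (the longest annotated transcript per symbol) and the position of Myct1 came from the GENCODE mouse annotation of GRCm38. Lengths were found for 96.1% of the shared genes. The RNA of Krt8 and Krt18 positive cells in the endothelial sums was estimated from 10 genes high in those clusters. Of these 10, Spp1 was higher still in knockout cluster 9, at 6880 CPM against 1847 CPM in the knockout Krt8 and Krt18 positive clusters.

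Alternatives fixed beforehand were trimmed mean of M-values (TMM) scaling with edgeR 4.0.16 in R 4.3.3, totals without ribosomal protein and mitochondrial genes, the mean over cells of each cell's CPM, thinning to 3000 UMIs per cell, a marker gate in place of clusters, a filter of at least 500 genes and at most 5% mitochondrial UMIs, no doublet removal, equal weights for endothelial subclusters, leaving out cycling cells, floors of 30 CPM and none, list members with at least 100 UMIs, clustering each library on its own, and resolutions 0.5 and 2. Alternatives chosen after the data had been seen were endothelial cluster 10 alone, removal of the estimated RNA of Krt8 and Krt18 positive cells, ratios relative to genes of like length, ratios relative to the Krt8 and Krt18 positive clusters, random lists matched on expression and length, random lists under equal subcluster weights, and those clusters taken 1 at a time.

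The procedure was tested on simulated data: endothelial sums drawn for the same depths with known changes in 200 genes. The 95% interval held the true ratio for 94.0% of 1502 unchanged genes, and 0 of these were counted as 2-fold different. Of 67 genes changed 2.5-fold, 65 were counted; of 66 changed 4-fold, 66 were counted; and of 67 changed 1.5-fold, 0 were counted. The interval held the true ratio for 91.0% of the genes changed 1.5-fold. For lists, a shift of 1 on the log2 scale was added to finished medians, with random lists not matched on expression. All 50 then lay beyond percentile 97.5, which that step largely fixed in advance. Of 50 lists without a shift, 2 lay below percentile 2.5 and 0 above 97.5. The simulated counts held counting error only, so false calls from transcript length or library were not tested.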

Results

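The data were 3' single-cell transcriptomes of tumour tissue from C57BL/6 mice, with 1 WT library and 1 Myct1 knockout library, each from 4 pooled mice. The WT library held 10880 barcodes and 115519153 UMIs, with a median of 8725.5 UMIs per barcode. The knockout library held 10700 barcodes and 145331950 UMIs, with a median of 12921. After filtering, 7870 WT and 7958 knockout cells were compared. There were no replicate libraries, so every difference below is between 2 libraries and was not tested; intervals are exact 95% intervals for counting error.

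Myct1, a small membrane protein gene known to be enriched in endothelium, was the gene targeted. Its level in WT endothelial cells was 246 CPM (231 to 263, 946 UMIs in 541 cells), and 71.7% of these cells held a Myct1 UMI (67.7 to 75.5%, median depth 6215 UMIs per cell). In WT fibroblasts the level was 0.61 CPM and 0.27% of cells held a UMI at a median depth of 8743 UMIs, and in the Krt8 and Krt18 positive clusters the level was 0.22 CPM and 0.34% held a UMI at 15532 UMIs. Mouse Myct1 (ENSMUSG00000046916.9) lies on the plus strand of chromosome 10 at 5593775 to 5606904 in GRCm38, with exon 1 at 5593775 to 5593901 and exon 2 at 5604187 to 5606904. The last 2206 bases of exon 2 hold the stop codon and 3' untranslated region, the part that a 3' assay mostly reads. Myct1 was not listed in the knockout table, which by the filter inferred for that table means at most 3 UMIs in any of its 10700 barcodes. In WT, 78 endothelial cells (14.4%) held at least 4 Myct1 UMIs, and at that share 43.1 of the 299 knockout endothelial cells would have done so. Of 906 genes enriched in WT endothelial cells, 179 had at least as many cells with 4 UMIs as Myct1 and were listed in both tables. At that bound, which its own count set, Myct1 was the only gene missing from the knockout table. In all, 129 of the 906 genes were missing from it, 11 of them with at least 3 such knockout cells expected at the WT share. After thinning to 3000 UMIs per cell, 50.3% of 489 WT endothelial cells held a Myct1 UMI (45.8 to 54.8%).

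The shares of cell classes describe what each library held, which dissection and digestion can also set. Endothelial cells, marked by genes such as Cdh5, Pecam1 and Kdr, made up 6.87% of WT cells (6.32 to 7.46%, 541 cells) and 3.76% of knockout cells (3.35 to 4.20%, 299 cells). Fibroblasts, the collagen-producing cells marked by Col1a1, Dcn and Pdgfra, made up 23.6% of WT cells (22.7 to 24.6%) and 0.314% of knockout cells (0.203 to 0.463%); the knockout share was 2.05% with each library clustered on its own, 0.691% at the finer resolution and 0.645% without doublet removal. Mural cells, the contractile cells around vessels marked by Rgs5 and Notch3, made up 1.28% (1.05 to 1.56%) and 0.478% (0.338 to 0.655%). Clusters positive for the keratins Krt8 and Krt18 and without a type name made up 52.0% of WT cells (50.9 to 53.1%) and 91.6% of knockout cells (90.9 to 92.2%). Cluster 9, an unnamed cluster with the fibroblast markers Col1a1 and Postn and with the mural genes Acta2 (914 CPM in WT) and Pdgfrb (429 CPM), made up 7.66% of WT cells and 0.817% of knockout cells. Lymphatic endothelial cells, marked by Prox1 and Lyve1, were 0.178% and 0.151% of cells, and epithelial cells with Epcam were 0.305% and 0.0754%. Macrophages or monocytes, marked by Csf1r and C1qa, were 27 WT cells (0.343%) and 7 knockout cells (0.0880%), too few for a comparison of expression. These shares leave out unnamed cluster 19 of very low depth, with 10 macrophage markers in 119 WT and 55 knockout cells. With each library clustered on its own the shares were 0.368% and 0.829%, the second from 66 cells with a median of 591 UMIs. In that clustering a WT cluster of 132 cells with 10 macrophage markers and a median of 592 UMIs stayed unnamed. The turned order therefore rests on naming. All unnamed cells outside the keratin positive clusters, cluster 9 included, were 15.4% and 3.56%.

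**Figure D1:**
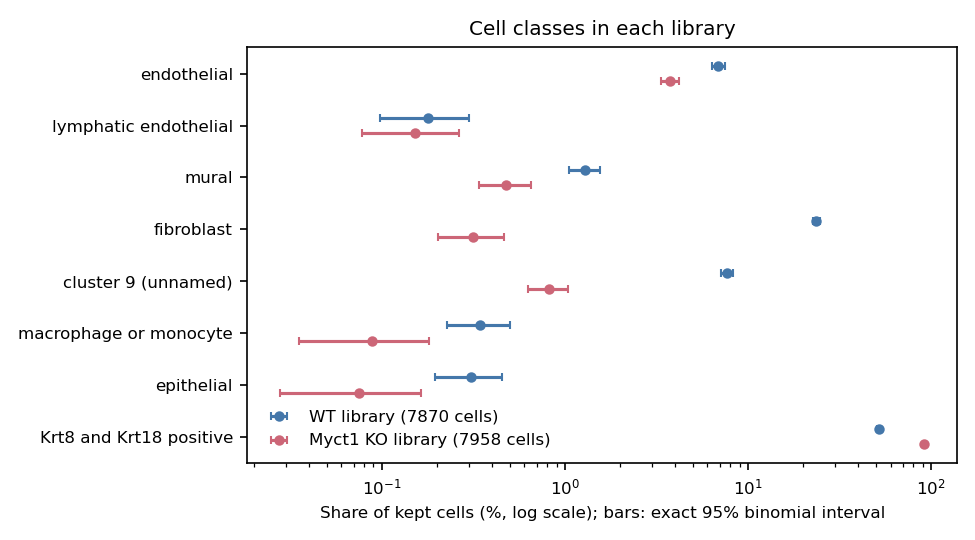
Share of kept cells in each class (log axis, percent) in the WT library (7870 cells) and the Myct1 knockout library (7958 cells); dots are shares and bars are exact 95% binomial intervals. Fibroblasts were 23.6% of WT cells and 0.314% of knockout cells, and Krt8 and Krt18 positive clusters were 52.0% and 91.6%.

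The comparison within the endothelium asks how tumour endothelial cells differ when Myct1 is targeted in them. Among genes reaching 100 CPM and within the free RNA limit, cell cycle genes led the higher ones by the lower interval bound. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, was 5.54-fold higher in knockout endothelial cells (log2 ratio 2.47, 2.20 to 2.75), and Birc5, the mitotic and survival factor survivin, was 5.11-fold higher (2.35, 2.05 to 2.66). The mitotic kinase gene Cdk1 had a log2 ratio of 1.75, Stmn1, which destabilises microtubules, 1.73, and the chromatin genes Hmgn2 and H2afz 1.66 and 1.33. Pgf, the placental growth factor that binds the receptor Flt1, was 2.77-fold higher (1.47, 1.30 to 1.64, but -0.0428 with the marker gate), and Higd1a, a mitochondrial protein gene induced by hypoxia, was 2.74-fold higher (1.45, 1.28 to 1.63). The remaining genes named at the top were Prdx4, a peroxiredoxin of the endoplasmic reticulum, at 1.64, Cacybp at 1.53, the early response gene Ier3 at 1.43 and the heat shock gene Hspa1a at 1.38.

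Among genes lower in knockout endothelial cells, Acer2, which encodes a ceramidase of the Golgi, was 9.18-fold lower (log2 ratio -3.20, -3.60 to -2.82). Cd36, the fatty acid translocase of capillary endothelium, was 5.99-fold lower (-2.58, -2.79 to -2.38), and Slco2a1, a prostaglandin transporter, was 5.93-fold lower (-2.57, -2.79 to -2.35). Tsc22d3 and Fkbp5, both known to be induced by glucocorticoids, had log2 ratios of -2.60 and -2.19. Insr, the insulin receptor, was at -2.21, Tacr1, the receptor of substance P, at -2.52, Cd300lg, a receptor of capillary endothelium, at -2.29, and the retinoid-binding protein gene Rbp7 at -2.55. The other named genes were Mcf2l at -2.56, the sulfhydryl oxidase gene Qsox1 at -2.28 and the tyrosine phosphatase gene Ptprg at -2.07. Rbp7 had a ratio of 0.03 within endothelial cluster 10, which held 279 WT and 297 knockout cells, and Mcf2l a ratio of 0.40 with subclusters weighted equally. Endothelial cluster 15 held 262 WT and 2 knockout cells, so these ratios also reflect which cells each library held. Subcluster 1 (180 WT and 1 knockout cells) had Acer2, Slco2a1, Tsc22d3, Tacr1 and Cd300lg among its top genes. Subcluster 4 (81 and 0 cells) had Acer2, Cd36, Rbp7 and Mcf2l. Within cluster 10, Rbp7 was the only named gene to turn direction.

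In all, of 1989 genes reaching 100 CPM in endothelial cells, 66 were at least 2-fold higher in the knockout library and 237 at least 2-fold lower. Of these, 12 and 17 were over the limit where free RNA could set them. The largest of these were Cenpa (2.16), Fabp5 (1.96) and Cks1b (1.91) among the higher, and the haemoglobin gene Hbb-bs (-6.94), Yam1 (-1.91) and Nr2f2 (-1.91) among the lower. The split rested on the scaling, since TMM gave 270 higher and 61 lower. Ratios relative to genes of like length also turned it, with 141 higher and 59 lower. More genes stayed lower with the marker gate (6 higher, 103 lower) and relative to the Krt8 and Krt18 positive clusters (38 higher, 57 lower). Depth limited the rarest genes: 1019 of the 9127 shared genes had fewer than 20 UMIs over both endothelial sums.

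**Figure D2:**
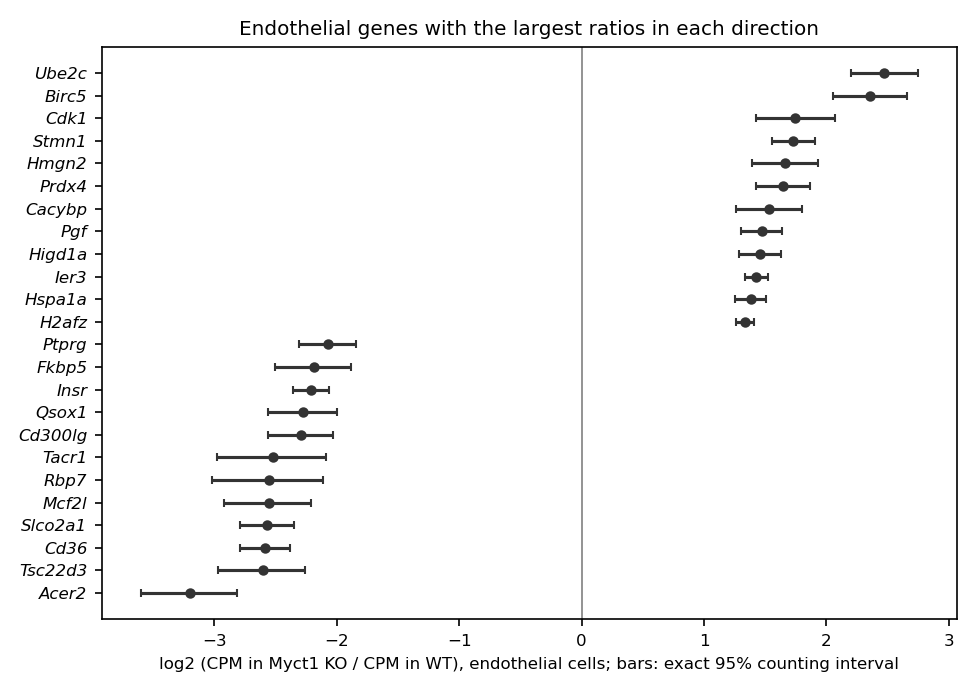
Log2 ratio of CPM in knockout over WT endothelial cells (x axis) for the 12 named genes in each direction; bars are exact 95% counting intervals. Ube2c lay at 2.47 and Acer2 at -3.20, at the ends of the 2 groups.

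Genes of cell division were higher together in knockout endothelial cells. Of 24 proliferation genes measured, 17 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 1.16 at percentile 100 of random lists matched on expression. That median was 0.71 within cluster 10, 0.45 without cycling cells, 0.42 with the marker gate and 0.18 with subclusters weighted equally, where its percentile was 87.1. Besides Ube2c and Birc5, the largest were the mitotic cyclin gene Ccnb1 (2.17) and the centromeric histone gene Cenpa (2.16), both over the free RNA limit. In 22 genes of hypoxia and glycolysis, 16 were higher and 1 was lower, with a median of 0.97 at percentile 100. The largest were Hk2 (3.49), Pgk1 (1.997) and Bnip3 (1.78), an induced hexokinase, a glycolytic kinase and a mitophagy receptor, all 3 over the free RNA limit, and Higd1a (1.45), which was not. Of 30 interferon response genes, 15 were higher and 1 lower, with a median of 0.62 at percentile 100; 18 of the 30 were over the free RNA limit, as were Ifit3 (2.66), Cxcl10 (2.15), Rtp4 (1.98) and Ifit1 (1.77), the largest. The interferon median was 0.17 within cluster 10, 0.0391 with equal weights (percentile 76.7) and -0.41 relative to the Krt8 and Krt18 positive clusters. The hypoxia median was 0.77 within cluster 10, 1.07 without cycling cells and 0.68 with equal weights, each at percentile 100. It was -0.06 when a marker gate, which took in mostly keratin positive cells in the knockout, replaced the clusters. Nuclear-encoded genes of oxidative phosphorylation, the respiratory chain of mitochondria, had a median of 0.46 with 7 of 25 higher and 1 lower; the percentile was 99.3 with matching on expression and 90.2 with length added.

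Endothelial transcription factor, identity and venous genes were lower in the knockout library. Of 17 Ets family and other endothelial transcription factor genes, 15 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -1.02 at percentile 0. Gata2 (-1.65), Foxc1 (-1.603), the hypoxia-inducible factor gene Epas1 (-1.39) and the Ets factor gene Fli1 (-1.16) were the largest. The median was -0.45 relative to genes of like length and -0.68 (percentile 0.11) with equal weights. Of 24 pan-endothelial identity genes, 16 were lower and 1 higher, with a median of -0.75 at percentile 0, among them Clec14a (-1.78), the phosphatase gene Ptprb (-1.68) and the VEGF receptor gene Kdr (-1.28); the median was -0.20 with equal weights, -0.31 relative to genes of like length and -0.22 relative to the Krt8 and Krt18 positive clusters. Of 12 venous genes, 10 were lower and 1 higher, with a median of -1.13 at percentile 0; Ackr1 (-1.92) and Nr2f2 (-1.91) were over the free RNA limit, and Lrg1 (-1.51) and the receptor gene Ephb4 (-1.31) were not, and the median was -0.40 with equal weights (percentile 12.8) and -0.48 relative to the Krt8 and Krt18 positive clusters. Of 11 genes of capillaries and fatty acid handling, 6 were lower and 1 higher, with a median of -1.15 at percentile 0.01, led by Cd36 and Cd300lg. That median was -0.43 within cluster 10, 0.18 with subclusters weighted equally and 0.65 relative to the Krt8 and Krt18 positive clusters. In those clusters all 20 measured pan-endothelial, 9 of 11 venous and all 9 capillary genes were over the free RNA limit. Ratios of these 3 lists relative to those clusters may therefore be divided by free RNA and do not set library apart from genotype. Shear stress and quiescence genes, with Timp3 (-1.76) and the anticoagulant receptor gene Thbd (-1.59), had a median of -0.78 with 6 of 10 lower, at percentile 0.57, -0.37 within cluster 10 and -0.22 with equal weights.

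Most other endothelial lists lay within the central 95% of random lists matched on expression. VEGF and angiopoietin genes and basement membrane genes lay below it, but not once length was matched as well. Genes of VEGF and angiopoietin signalling had a median of -0.75 (8 of 15 lower, 3 higher, percentile 0.905), with Pgf at 1.47 against Kdr at -1.28, Aplnr at -1.23 and Nrp1 at -1.13. Tip cell genes had a median of -0.30 (percentile 13.9), with Pgf, Kcne3 (1.01) and Adm (0.96) higher and Plxnd1 at -1.03. Arterial genes had a median of -0.73 (percentile 5.72), Notch signalling -0.53 (20.2), tight and adherens junctions -0.54 (4.41), leukocyte adhesion -0.22 (43.7), and basement membrane and matrix -0.48 (1.47). MHC class I genes, which present peptides to T cells, had a median of 0.06 (percentile 88.5) with the immunoproteasome gene Psmb8 at 1.30, and MHC class II had 2 measured genes, H2-Ab1 (0.58) and Cd74 (-0.13), both over the free RNA limit. Chemokines and cytokines had a median of 0.06 (95.4), with Ccl21a at 3.79, Csf3 at -3.00 and, over the free RNA limit, Ccl2 at 2.24. Ccl21a is a lymphatic endothelial marker, and that class (14 WT and 12 knockout cells) was below the 20 cells the free RNA check required. At resolution 2, an unnamed endothelial subcluster of 15 WT and 17 knockout cells had Ccl21a, Lyve1 and Mmrn1 among its top genes. T cell inhibitory ligands had a median of -0.43 (25.6). The unfolded protein response had a median of 0.05 (81.6). Mesenchymal transition genes had a median of -0.22 (36.9) and a mean of 0.0047, and immediate early and dissociation stress genes a median of -0.07 (16.5) and a mean of 0.11. Medians near 0 turned under some alternatives: with equal weights mesenchymal genes were at 0.41, immediate early genes at 0.48 and MHC class I genes at -0.21, and relative to genes of like length tip cell genes were at 0.19. The alternatively activated macrophage and lymphocyte lists held 3 or fewer measured genes in endothelial cells. The alternatively activated list had a median of 0.85 (Spp1 2.64, Stab1 -0.99, Vegfa 0.85), which turned to -0.51 with the marker gate and -0.60 with equal weights. Of its 3 genes 2 were over the free RNA limit. Spp1 was 1 of these, at 98.5 CPM in knockout endothelial cells against 1847 CPM in the knockout Krt8 and Krt18 positive clusters. The exhaustion list had a median of -1.11 (Lag3 alone), and 0 genes of the cytotoxic list were measured.

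Signs of RNA quality and of the libraries themselves also differed. Mitochondrially encoded genes had a median of -0.28 (percentile 4.22), and the nuclear RNAs Malat1, Neat1, Kcnq1ot1 and Meg3 had log2 ratios of 0.13, -0.55, 0.13 and -4.09. Of sex-linked genes, Xist and Tsix were at -0.92 and -0.96, and Y-linked genes were not in both tables. Of genes near Myct1 on chromosome 10, Syne1 (-0.89), Zbtb2 (-0.97) and Akap12 (-1.07) were lower and Fbxo5 (2.65) was higher. Ratios followed transcript length in every cell set: in endothelial cells the median log2 ratio went from 0.43 for genes under 1000 bases to -0.80 for genes of 8000 bases or more. The same ends were 0.29 and -0.42 in the Krt8 and Krt18 positive clusters and 0.35 and -0.36 in cluster 9. Across genes, which are not independent replicates, the rank correlation of length and ratio was -0.51 (7786 genes), -0.47 (8483 genes) and -0.33 (8171 genes) in these sets. With random lists matched on length as well, proliferation, hypoxia and interferon stayed at percentile 100, venous and capillary genes at 0, Ets and endothelial transcription factors at 0.01, pan-endothelial identity at 0.18 and shear stress at 0.57. Basement membrane genes were then at percentile 75.01, junction genes at 44.5, VEGF and angiopoietin genes at 5.62 and mitochondrially encoded genes at 0.01.

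**Figure D3:**
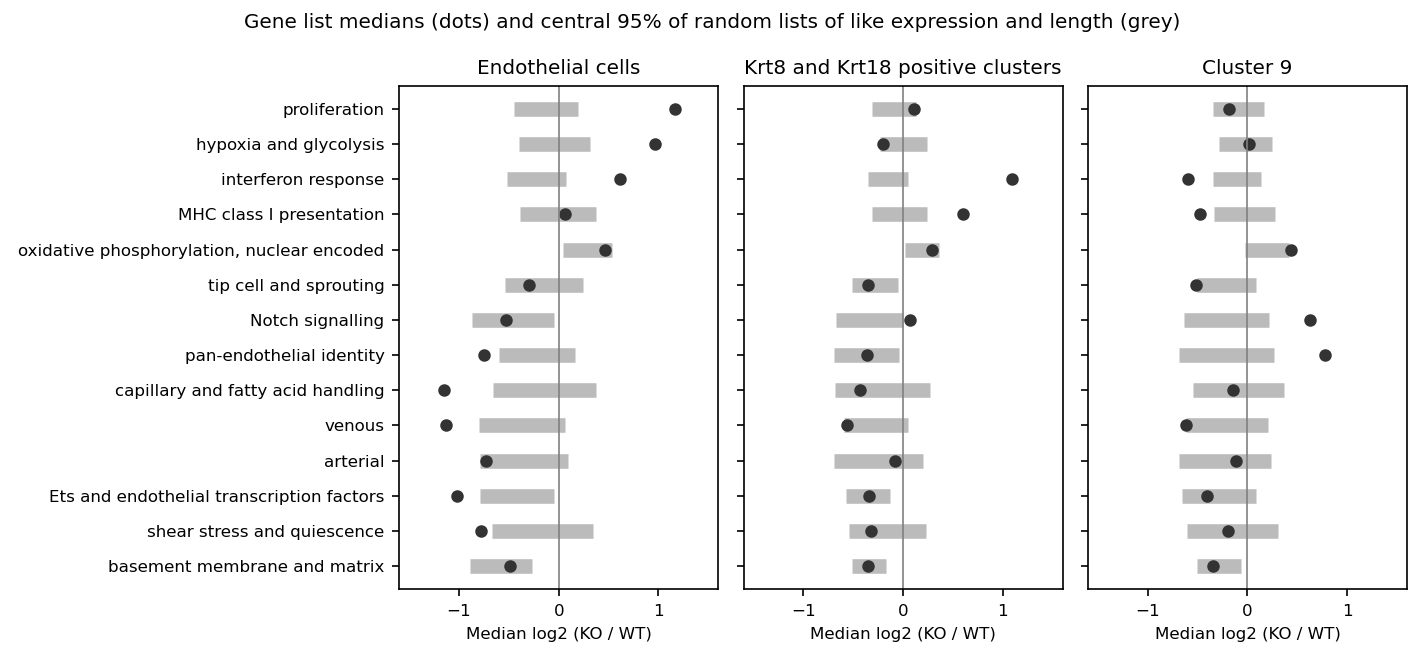
Median log2 ratio of knockout over WT (x axis) of selected gene lists in endothelial cells, in the Krt8 and Krt18 positive clusters and in cluster 9; dots are list medians and grey bars are the central 95% of random lists of like expression and length. In endothelial cells proliferation lay at 1.16 and Ets and endothelial transcription factors at -1.02, outside their bars.

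**Figure D4:**
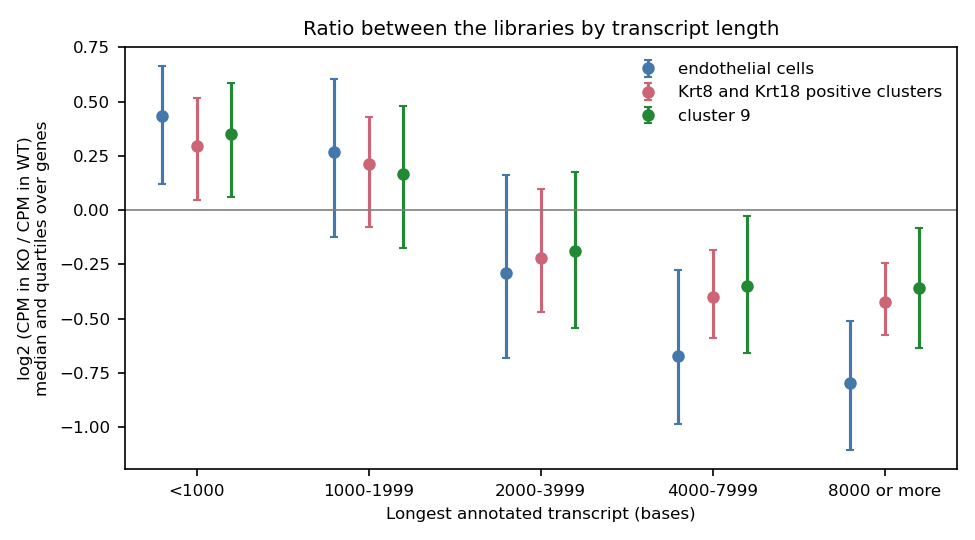
Log2 ratio of knockout over WT (y axis) by longest annotated transcript in bases (x axis) in the 3 cell sets; dots are medians and bars are quartiles over genes. Medians in endothelial cells went from 0.43 for the shortest genes to -0.80 for the longest.

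Endothelial subclusters divided largely along library lines. The cycling subcluster, with Mki67 and Top2a, held 4.44% of WT endothelial cells (2.86 to 6.53%, 24 of 541) and 15.4% of knockout cells (11.49 to 19.98%, 46 of 299), and stayed within these intervals under every alternative clustering. The arterial subcluster, with Gja4, Efnb2 and Hey1, held 14.97% of WT cells (12.1 to 18.3%) and 0 of 299 knockout cells, which allows a share of up to 1.00%. The 0 belongs to the joint clustering. With each library clustered on its own, an unnamed subcluster of 80 knockout cells had the arterial genes Gja4, Cxcl12 and Stmn2 among its top genes, beside the venous gene Selp. The venous subcluster, with Nr2f2, Selp and Ackr1, held 13.7% of WT cells (10.9 to 16.9%) and 4.35% of knockout cells (2.34 to 7.32%). Over the alternative clusterings that named one, the venous share ran from 6.65% to 22.4% in WT and from 2.34% to 7.69% in the knockout. The tip subcluster, with Apln, Angpt2 and Dll4, held 29.6% of WT cells (25.8 to 33.6%) and 6.35% of knockout cells (3.87 to 9.75%), an order that turned with the stricter cell filter (36.9% and 44.2%), with each library clustered on its own (22.4% and 33.3%) and at the finer resolution (33.6% and 42.3%). Unnamed subclusters 0 and 1 held 4.07% and 33.3% of WT cells and 73.6% and 0.334% of knockout cells. Because the defining genes themselves differed between libraries, subcluster shares are not read as sizes of vessel types.

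In the Krt8 and Krt18 positive clusters, which are not endothelial, the comparison shows how the other main cell set of the 2 libraries differed. Interferon genes stood out: Isg15, a ubiquitin-like antiviral protein, was 3.598-fold higher in the knockout library (log2 ratio 1.85, 1.79 to 1.91, 4090 WT and 7288 knockout cells), and 24 of 31 interferon genes were at least 1.5-fold higher and 0 lower, with a median of 1.09 at percentile 100. The largest of these, Cxcl10 (2.76), Ifit3 (2.30), Cxcl9 (2.22) and Rsad2 (2.02), were over the free RNA limit, as were 23 of the 31. The cells of the libraries sat in different clusters, with 20 WT and 1590 knockout cells in cluster 2 and 1252 and 372 in cluster 1. Within the 7 clusters with 50 cells of each library, Isg15 ran from 0.47 to 1.62 and the interferon median from -0.0874 in cluster 12 to 1.29 in cluster 1. Of these, cluster 4 had interferon genes such as Ifit3 and Isg15 among its top genes and held 250 WT and 1049 knockout cells. Clusters 2, 5, 11 and 14 had too few cells of 1 library for this check. MHC class I genes had a median of 0.60 (9 of 17 higher, percentile 100, 15 over the free RNA limit), with the immunoproteasome genes Psmb8 at 1.72 and Psmb9 at 1.37, but taken 1 cluster at a time only 3 of 7 medians lay above the random lists and the medians ran from -0.42 to 0.47. Summed over clusters, the 6 measured MHC class II genes had a median of 1.47: H2-Ab1 2.60, Cd74 2.22, H2-Eb1 1.55, H2-Aa 1.38, Ctss 0.48 and H2-DMa -0.25, all over the free RNA limit. The other named genes were Ier3 (1.36), Gpx8 (1.10), the platelet-activating factor hydrolase gene Pla2g7 (1.08, and 0.15 to 1.28 within clusters) and Prdx4 (1.02, and 0.39 to 1.09 within clusters) among the higher, with Id3 (1.21, and 0.18 to 0.60 within clusters) and Spp1 (0.96, and -0.20 to 0.75 within clusters) over the free RNA limit. Rnf19b (-1.13), the oxidase gene Ero1l (-1.06), Erdr1 (-0.99) and the stress transcription factor gene Ddit3 (-0.99, and -0.94 to -0.35 within clusters) were the lower ones, with Yam1 (-1.97), Tnc (-1.003) and Gpc1 (-0.98) over the limit. Unfolded protein response genes had a median of -0.38 (6 of 15 lower, percentile 2.36), with Ddit3, Trib3 (-0.98) and Atf4 (-0.69); within single clusters the medians ran from -0.40 to -0.03 and 0 of 7 lay below the random lists, and Ero1l was at 0.94 in cluster 6. Proliferation genes had a median of 0.11 (4 of 24 higher, 0 lower, percentile 98.7), with 3 positive and 4 negative medians within clusters. Among them were 0.24 in cluster 0 (percentile 100), 0.24 in cluster 1 (99.99) and -0.31 in cluster 7 (1.13). Hypoxia genes had a median of -0.20 (percentile 7.77), with 0.53 in cluster 6. Immediate early and dissociation stress genes, Ier3 among them, had a median of 0.29 (6 of 22 higher, 0 lower, percentile 98.3, 16 over the free RNA limit). Within single clusters 3 of 7 of their medians lay above the random lists. Of 1433 genes reaching 100 CPM, 8 were at least 2-fold higher and 7 at least 2-fold lower, and TMM gave 32 and 2.

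Cluster 9, with 603 WT and 65 knockout cells, was the other set compared; cluster 19, with 119 and 55 cells was not compared for its low depth (median 594 UMIs). The nuclear receptor gene Rorb was 9.71-fold higher in the knockout library (log2 ratio 3.28, 2.88 to 3.68), and the matrix protein gene Thbs4 (2.33), the retinoic acid binding protein gene Crabp1 (1.69), Fdps of cholesterol synthesis (1.54) and Gng11 (1.25) followed. Mmp3, a matrix metalloproteinase gene, was 4.29-fold lower (-2.10, -2.30 to -1.91), followed by the alarmin gene Il33 (-1.85), Man2a1 (-1.76), Car4 (-1.84) and Flrt2 (-1.87). All but Man2a1 had their highest level outside cluster 9 in WT fibroblasts, for Mmp3 2373 CPM against 910 CPM in WT cluster 9. Fibroblasts were 23.6% of WT and 0.314% of knockout cells, and a part of their RNA in these ratios was not tested. Genes over the free RNA limit included Lgals7 (2.55), S100a4 (2.002) and Hspb1 (1.84) among the higher and Pi16 (-3.87), Ctla2a (-2.76) and Yam1 (-2.57) among the lower. Chemokines and cytokines had a median of -0.95 (10 of 17 lower, 2 higher, percentile 0), with Cxcl5 at -2.73, Il6 at -2.05 and Ccl2 at -1.53, and VEGF and angiopoietin genes a median of -1.003 (7 of 14 lower, percentile 0), with Angpt1 at -2.85. Interferon genes had a median of -0.60 (10 of 28 lower, 1 higher, percentile 0.06) and MHC class I genes a median of -0.47 (7 of 17 lower, percentile 1.23), with 21 and 13 members over the free RNA limit. Notch signalling (0.62, percentile 99.9), nuclear-encoded oxidative phosphorylation (0.44, percentile 99.9) and tight and adherens junctions (0.44, percentile 99.8) lay above their random lists. Of the 13 junction genes 10 were over the free RNA limit, pan-endothelial identity genes, all over it, had a median of 0.78, and after thinning these medians were -0.0876 and -0.30. Of 1707 genes reaching 100 CPM, 17 were at least 2-fold higher and 92 at least 2-fold lower; 5 and 49 of them were over the free RNA limit, and thinning to 3000 UMIs per cell gave 59 and 154. Across genes, the log2 ratios of the 3 sets went together, with Pearson r 0.84 between endothelial cells and the Krt8 and Krt18 positive clusters (1163 genes), 0.70 between endothelial cells and cluster 9 (1232 genes) and 0.77 between those clusters and cluster 9 (1008 genes).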

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

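The tests of RNA from Krt8 and Krt18 positive cells, of the whole library, of endothelial cluster makeup and of dilution were chosen after the results had been seen. Leaving out cycling cells and equal subcluster weights were alternatives fixed beforehand, but their bounds were written after the results had been seen. The bounds for gene length and for keratin cluster makeup were written after the main ratios had been seen but before those tests were run. The 3 patterns below were found and tested in the same 2 libraries, and a difference of library or batch cannot be told apart from genotype for any of them.

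Some gene lists stood apart because they differed in size or direction between cell sets; the differences were not tested. The pan-endothelial identity median was -0.75 in endothelial cells, -0.36 in the Krt8 and Krt18 positive clusters and 0.78 in cluster 9, where all 15 measured members were over the free RNA limit and thinning to 3000 UMIs per cell turned the median to -0.30. MHC class I medians were 0.0638, 0.60 and -0.47 in the same order, interferon medians 0.62, 1.09 and -0.60, and chemokine and cytokine medians 0.0633, 0.41 and -0.95.

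Cluster 20, 48 WT and 92 knockout cells of very low depth, stood apart for salivary gland transcripts that no comparison used. Levels in WT and knockout cells of this cluster were 40584 and 17440 CPM for Bpifa2, 19690 and 8742 CPM for Smr3a, 5606 and 2299 CPM for the amylase gene Amy1, and 2942 and 1589 CPM for the carbonic anhydrase gene Car6; these differences were not tested.

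Proliferation genes such as Ube2c and Birc5 were higher in knockout endothelial cells. RNA of Krt8 and Krt18 positive cells could raise them, but with the largest share of it taken out of the knockout profile alone the median was 1.20, against an upper end of 0.11 for random lists. Among lists matched on length the percentile was 100, which argues against gene length. Without the cycling subcluster the median was 0.45 against an upper end of 0.05, but with equal subcluster weights, which used 46 WT cells, it was 0.18 at percentile 87.1, inside the random lists, so a larger share of cycling cells stays open as the cause. Cells with cycling genes also made up more of the Krt8 and Krt18 positive cells, which are not endothelial, in the knockout library. There, clusters 7 and 12 had Ube2c and Birc5 among their top genes. They held 217 and 115 of 4090 WT cells and 753 and 319 of 7288 knockout cells. More division of endothelial cells after targeting of Myct1 is an untested hypothesis, with library or batch as the open alternative.

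Interferon genes such as Ifit3 and Cxcl10 were higher in endothelial cells and in the Krt8 and Krt18 positive clusters of the knockout library. Both genes, and most measured members of the list, were over the free RNA limit in both sets. Only RNA of Krt8 and Krt18 positive cells was taken out, so free RNA of other classes was not tested. For endothelial cells, taking out the largest share of RNA from Krt8 and Krt18 positive cells left a median of 0.63 against an upper end of -0.03, and a shift of every cell set of the library would raise cluster 9 too, where the median was -0.60, which argues against both, though 21 of the 28 members there were over the free RNA limit. Within cluster 10 the median was 0.17 against an upper end of -0.0084, but with equal subcluster weights it was 0.0391 at percentile 76.7, so endothelial makeup stays open. In the Krt8 and Krt18 positive clusters, 6 of the 7 with 50 cells of each library lay above the central 95% of random lists, short of the every cluster bound written before (cluster 12 lay at 97.35), so cluster makeup stays open. A response to interferon in the knockout tumours may be one explanation, untested here.

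Ets and endothelial transcription factor genes such as Gata2, Epas1 and Fli1 were lower in knockout endothelial cells. Their percentile was 0.01 among lists matched on length and 0.01 within cluster 10, and 0.11 with equal subcluster weights (46 of the 541 WT cells, 22 of them at a median of 1167 UMIs), which argues against gene length and against the makeup by the 2 endothelial clusters as whole causes. Dilution by RNA of Krt8 and Krt18 positive cells would have needed a share of 44.3%, and the largest measured share was 6.39%. Lower expression of these factors after targeting of Myct1 is a hypothesis that could be set apart from library or batch only with more libraries.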

How the results depend on the processing

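The alternatives with cluster 10 alone, RNA of Krt8 and Krt18 positive cells taken out, genes of like length and ratios relative to the Krt8 and Krt18 positive clusters were chosen after the data had been seen. Over all alternatives, 1116 values were computed: 818 stayed within their spread, 285 moved beyond it, and 13, of named genes or of lists outside their random lists, turned direction. With lists inside their random lists included, 81 of 973 medians and ratios changed sign. A setting fixed beforehand for normalised values did not apply, since the files held raw UMIs. Except where stated, the cause was not tested. Alternatives that named no cluster of a class gave no value for it.

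TMM, which scales to the middle of all genes, gave 270 genes higher and 61 lower in endothelial cells, 32 and 2 in the Krt8 and Krt18 positive clusters and 40 higher in cluster 9, with interferon medians of 0.94 in endothelial cells and 1.32 in the Krt8 and Krt18 positive clusters. Totals without ribosomal protein and mitochondrial genes gave 106 endothelial genes higher. Thinning to 3000 UMIs per cell gave 104 endothelial genes higher, 17 higher in the Krt8 and Krt18 positive clusters, and 59 higher and 154 lower in cluster 9, where the interferon median was -1.05, pan-endothelial identity -0.30 and junctions -0.0876. A floor of 30 CPM gave 149 endothelial genes higher and 720 lower, and no floor 305 and 1229, since more genes were counted. With members of at least 100 UMIs the capillary median was -0.49.

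The marker gate took in 475 WT and 1115 knockout cells of the Krt8 and Krt18 positive clusters beside 450 and 293 endothelial cells, which lowered WT Myct1 to 59.6 CPM. It gave 6 genes higher and 103 lower, with medians of -2.11 for pan-endothelial identity, -1.39 for tip cells, 0.42 for proliferation, -0.0610 for hypoxia, -1.6003 for Ets factors and -0.51 for the alternatively activated list, and Pgf at -0.0428. Equal weights could use 2 of 6 subclusters (46 WT and 266 knockout cells): 127 genes were lower, and medians were -0.20 for pan-endothelial identity, -0.40 for venous, 0.18 for capillary, 0.0391 for interferon, 0.18 for proliferation and -0.60 for the alternatively activated list, with Mcf2l at 0.40. Without cycling cells the proliferation median was 0.45. Cluster 10 alone gave 42 genes higher, medians of -0.43 for capillary, 0.17 for interferon and 0.71 for proliferation, and Rbp7 at 0.0312.

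Relative to genes of like length, 141 endothelial genes were higher and 59 lower, with medians of -0.31 for pan-endothelial identity, 0.19 for tip cells, -0.50 for capillary, -0.45 for Ets factors and 0.0139 for basement membrane genes. Relative to the Krt8 and Krt18 positive clusters, 38 were higher and 57 lower, with medians of -0.22 for pan-endothelial identity, -0.48 for venous, 0.65 for capillary, -0.63 for MHC class I and -0.41 for interferon, and Yam1 at 0.0620. Free RNA could set the divisor of these lists. In those clusters all 20 pan-endothelial, 9 of 11 venous and all 9 capillary genes were over the free RNA limit. So were 15 of 17 MHC class I and 23 of 31 interferon genes. With RNA of those clusters taken out, all 63 values stayed within their spread.

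Shares also moved. The stricter cell filter gave 5.75% endothelial cells in WT, and in WT and knockout 29.9% and 0.465% fibroblasts, 48.6% and 93.9% Krt8 and Krt18 positive cells, 1.03% and 0.340% macrophages or monocytes, 36.9% and 44.2% tip cells and 10.4% and 7.69% venous cells. Without doublet removal endothelial cells were 7.49% and 4.32%, fibroblasts 25.1% and 0.645%, Krt8 and Krt18 positive cells 50.5% and 90.9%, and WT Myct1 was 212 CPM. With each library clustered on its own fibroblasts were 21.7% and 2.05%, knockout Krt8 and Krt18 positive cells 90.4%, knockout macrophages or monocytes 0.829%, tip cells 22.4% and 33.3%, WT venous cells 22.4% and WT arterial cells 18.9%. The share of 0.829% rested on naming, since a WT cluster of 132 cells with macrophage markers stayed unnamed. WT venous cells were 6.65% at the coarser resolution and 20.5% at the finer, where fibroblasts were 27.3% and 0.691%, knockout Krt8 and Krt18 positive cells 90.9% and tip cells 33.6% and 42.3%.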

Other observations

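All values in this part were picked out after the data had been seen, and none was tested. Some genes differed the same way in endothelial cells, the Krt8 and Krt18 positive clusters and cluster 9. Yam1 had log2 ratios of -1.91, -1.97 and -2.57, but it was over the free RNA limit in all 3, with 53655 CPM in WT cluster 22. Relative to the Krt8 and Krt18 positive clusters its endothelial ratio was 0.0620. The glucocorticoid-induced genes Tsc22d3 and Fkbp5 were at -2.60, -0.71 and -0.49 and at -2.19, -0.45 and -0.52. Ier3 (1.43, 1.36 and 0.46) and Prdx4 (1.64, 1.02 and 0.56) were higher in all 3. Xist, expressed from the inactive X chromosome of females, was at -0.92, -0.66 and -0.37. Among random lists matched on length as well, Xist and Tsix together lay at percentile 20.9 in the Krt8 and Krt18 positive clusters and 37.9 in cluster 9. Cluster 8, with Xist at 16.8 CPM, held 17.2% of WT and 1.85% of knockout Krt8 and Krt18 positive cells.

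Of genes enriched in WT endothelial cells and not listed in the knockout table, the synaptic scaffold gene Shank3 came next after Myct1 in level, at 144.8 CPM with 25 cells of at least 4 UMIs; 13.8 knockout cells would have held as many at the WT share. In endothelial sums, ribosomal protein genes held 17.2% of WT UMIs and 21.1% of knockout UMIs.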
